A study of Mus musculus with 6 samples.

How the data were processed

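The samples were sorted erythroid progenitors from the bone marrow of 3 control and 3 Bcl11a knockout mice. Per the labels' protocols, total RNA was extracted with Trizol and biotin-labelled cRNA was hybridised to Affymetrix arrays, 1 array per mouse. The labels name the mice as separate animals, so the p-values of single probe sets measure the spread between mice. All 6 arrays were compared in the 1 contrast that the labels give, knockout against control.

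The authors deposited 1 table with an intensity on a linear scale for each probe set and array. The software that summarised the probes, the background correction and the scaling are not given in the sources used here. The values bear 2 marks of earlier processing. The array medians lay between 67.5 and 70.9, so the arrays had been brought to a common level, and between 775 and 874 values per array (1.72% to 1.94%) were exactly 1.00, while 2 to 7 values per array lay below 1, down to 0.58. How low values were treated is not given in the sources used here, and changes of the dimmest probe sets depend on it. There were no detection calls. For arrays, the number of mice limits the precision, and 3 against 3 cannot give an exact two-sided permutation p below 0.1.

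The array annotation of the platform gave 1 gene symbol for 34945 of the 45037 probe sets, several for 932 and none for 9160. Through Entrez IDs, 34741 of the single-symbol probe sets matched a RefSeq gene of the mouse assembly GRCm38.p6, which was used only for names and for which genes neighbour each other. Together they named 18193 genes. A probe set with several symbols named no gene. A gene stood for its brightest single-symbol probe set, and for named genes that passed the test, probe sets that moved the other way are given beside it.

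Before the data were examined, it was fixed that linear values would become log2(intensity + 16), and that arrays would be normalized again only if their log2 medians or interquartile ranges differed by more than 0.1. They differed by at most 0.057 and 0.070, so the deposited values were used. A log2 change on this scale understates the change of dim probe sets. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without an intensity trend, two-sided), with Benjamini-Hochberg adjustment over all 45037 probe sets and an adjusted p threshold of 0.05. No dim probe set was left out. The prior degrees of freedom were 2.42 and the median residual SD was 0.21 on the log2 scale. Means and SDs are of linear intensities over 3 mice, errors of log2 changes are standard errors from the fit, and ratios are of mean intensities.

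Also fixed beforehand were 32 gene lists, of which 29 had at least 5 measured genes and were tested with limma's camera at a preset correlation of 0.01, adjusted over the 29 lists. Of these, 14 passed. The preset correlation takes the genes of a list as nearly independent. These p-values therefore do not measure the spread between mice alone. With an estimated correlation 0 passed (lowest adjusted p 0.495), and with fry, which tests whether a list's genes move on balance one way, 0 passed. Members were counted past the threshold over all probe sets and adjusted over the list alone. The lists share some members, such as Tal1 and Gata2.

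The genes named are Bcl11a, every measured globin, the 12 genes with the largest rise and the 12 with the largest fall past the threshold with groups that do not overlap (or, with fewer than 5 in a direction, the 5 with the smallest p and groups that do not overlap, said not to have passed), and up to 4 members of each list by p. Sex-linked genes served as a check of the labels. Klf6 and 4930447F24Rik were named through a probe set that is not their brightest.

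The fit was tested on simulated data in which 200 of the 45037 probe sets were changed, all drawn from the brighter 50%. It recovered 100% of those raised by 2 log2 units, 52% of those raised by 1, 64% of those lowered by 1 and 90% of those lowered by 2, and 4.4% of its calls were false. With an intensity trend and robust moderation these shares were 100%, 68%, 72%, 94% and 1.2%. A simulated list of 20 genes shifted by 0.5 log2 units was called by camera, and 1 of 100 lists without a shift had a p under 0.05. The simulated noise was independent between probe sets. Recovery of dim changes, and false calls by camera among genes that vary together, were therefore not tested.

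Alternatives fixed beforehand were quantile normalization, median centring, pseudocounts of 1 and 64, the brightest 50% and 25% of probe sets, an intensity trend with robust moderation, array weights, 1 probe set per gene, the replicate number as a block, leaving out each mouse, a log2 change of at least 1, and for lists an estimated correlation and the mean of all probe sets of a gene. Cyclic loess normalization and leaving out probe sets with a value of exactly 1.00 were added after the data were seen. A planned check of RNA quality from the control probe sets was not made because the table used held 0 of them. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.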

Results

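Gene expression was measured on Affymetrix arrays in erythroid progenitors from the bone marrow of 6 female mice that were 6 weeks old. The cells were sorted for CD71, the transferrin receptor, and Ter119, an erythroid surface antigen. In 3 control mice Bcl11a was intact. In the 3 mice called knockout, Bcl11a was flanked by sites for the Cre recombinase, which was expressed under the control of the erythropoietin receptor gene. Each mouse gave 1 array. The median intensity of the 45037 probe sets lay between 67.5 and 70.9 on the 6 arrays, and the upper quartile between 331 and 337. Log2 values correlated across probe sets at r = 0.981 to 0.986 within the groups and at r = 0.980 to 0.983 between them; probe sets are not independent replicates. Xist, which female cells express, had a mean intensity of 9395 in the controls and 9417 in the knockouts, and the 3 measured Y-linked genes, Uty, Kdm5d and Eif2s3y, had group means between 19.6 and 34.8.

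The comparison of knockout with control mice asked which transcripts of adult erythroid progenitors change when Bcl11a, which encodes a transcriptional repressor of developmentally silenced globin genes, is inactivated in the red cell lineage. Bcl11a itself was read by 7 probe sets, and none passed the test. The brightest had an intensity of 1492 ± 53.9 in the controls and 1298 ± 115 in the knockouts (SD, n = 3), a log2 change of -0.20 ± 0.11 (SE, adjusted p = 0.503). The other 6 had log2 changes between -0.40 and 0.32, with 2 above 0 and 4 below. In all 7 but the probe set with a change of -0.03, the groups did not overlap, in the direction of the change. The exact permutation p was 0.1 for each of these, and 19.5% of all probe sets had groups that did not overlap. Where these probes lie relative to the deleted part of the gene is not given in the sources used here, so their level neither supports nor contradicts the genotype labels. Cre was named for the knockout mice only, so an effect of Cre or of the altered erythropoietin receptor allele could not be separated from that of Bcl11a. Strain backgrounds are not given in the sources used here, so a difference in background could not be separated either.

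The embryonic globin genes rose more than any other named gene. Hba-x, the embryonic zeta globin, had an intensity of 23.1 ± 9.60 in the controls and 19646 ± 1651 in the knockouts (SD, n = 3), an increase of 9.0 ± 0.19 on the log2 scale (SE, adjusted p = 2.39e-05). Hbb-y, the embryonic epsilon-y globin, went from 73.3 ± 6.91 to 19621 ± 434, an increase of 7.78 ± 0.10 (adjusted p = 4.49e-06). Hbb-bh1, the embryonic beta-h1 globin, went from 63.3 ± 8.95 to 5294 ± 1545, an increase of 6.03 ± 0.24 (adjusted p = 0.000619). The ratios of the listed mean intensities were 852 for Hba-x, 268 for Hbb-y and 83.6 for Hbb-bh1, and they are approximate.

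All 3 probe sets of Hbb-y, all 3 of Hbb-bh1 and the 1 of Hba-x passed the test, with log2 increases from 6.03 to 9.0. In the controls Hba-x stood at percentile 26.5 of all probe sets, Hbb-bh1 at percentile 48.3 and Hbb-y at percentile 51. In the knockouts they stood at percentiles 99.8, 97.6 and 99.8. The 3 knockout mice had Hbb-bh1 intensities of 3624, 6672 and 5586, a wider relative spread than for Hbb-y, whose values were 19266, 20104 and 19491. Every knockout value lay above every control value for all 3 genes, and the two-sided exact permutation p was 0.1 for each, the smallest that 3 against 3 mice allow. The deposited values held no detection calls, so the control levels cannot be told from background. The knockout intensities of Hba-x and Hbb-y, at percentile 99.8, were near those of adult globin probe sets and below the array maxima of 38113 to 40360. Intensities of different probe sets do not compare amounts of RNA, since the 3 probe sets of Hbb-y had knockout means of 19621, 19624 and 9670. Whether signals this high were saturated was not tested. The ratios depend on both ends of the range.

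The adult globins did not pass the test. The probe set shared by the adult beta globin genes had an intensity of 19064 ± 398 in the controls and 16681 ± 1777 in the knockouts (SD, n = 3), a log2 change of -0.20 with a 95% interval from -0.47 to 0.08 (adjusted p = 0.536). The 3 probe sets shared by the adult alpha globins Hba-a1 and Hba-a2 had log2 changes of 0.08, -0.17 and -0.25. In the shared beta probe set and the alpha ones with changes of -0.17 and -0.25, every knockout value lay below every control value. The brighter probe set annotated to Hbb-b2 alone had 14184 ± 967 and 17117 ± 1497, a log2 change of 0.27 ± 0.11 (SE, adjusted p = 0.413), with every knockout value above every control value. The dimmer one had 17.6 ± 15.7 and 31.2 ± 12.2, a change of 0.55 (adjusted p = 0.572). The dimmer single-gene probe sets of Hba-a2 and Hba-a1 had log2 changes of 0.46 (adjusted p = 0.350) and 0.14 (adjusted p = 0.808). These genes are near-identical copies, so probes can be shared between them. The shared probe sets lay at percentiles 99.6 to 100 of all probe sets, on arrays whose maxima were 38113 to 40360. Whether saturation hid a change in them was not tested.

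**Figure D1:**
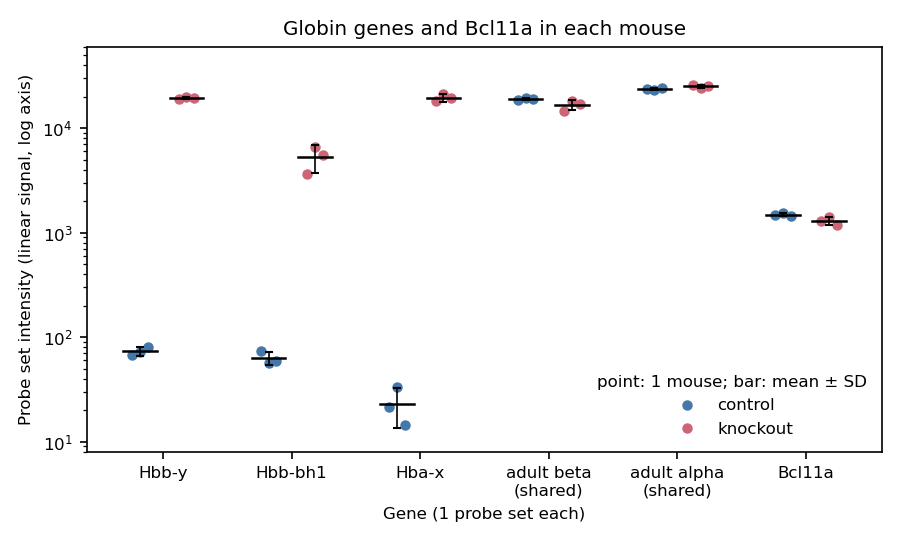
Intensity on a log axis of 1 probe set for each embryonic globin, the shared adult beta and alpha probe sets and Bcl11a, with 1 point per mouse and bars for the mean and SD of the 3 mice of a group. The highest embryonic globin value of a control mouse was 80.9 and the lowest of a knockout mouse 3624, while the changes of the adult globins and Bcl11a did not pass the test.

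Across all probe sets, 63 rose and 3 fell (limma, adjusted p threshold of 0.05), which stood for 44 genes that rose and 3 that fell. After the embryonic globins, the largest rises were in genes with varied known roles. Gng13, a G protein gamma subunit best known from taste and retinal signalling, went from 16.1 ± 8.19 to 781 ± 81.0, an increase of 4.66 ± 0.19 on the log2 scale (SE, adjusted p = 0.000772). Amot, a scaffold protein of the Hippo pathway, went from 55.3 ± 5.45 to 780 ± 133, an increase of 3.47 ± 0.15 (adjusted p = 0.000787). Cox6b2, the testis form of a cytochrome c oxidase subunit, went from 860.0 ± 150 to 6019 ± 476, an increase of 2.80 ± 0.16 (adjusted p = 0.00279). Itga2b, the integrin CD41 of platelets and of the earliest blood progenitors, went from 513 ± 44.6 to 3520 ± 274, an increase of 2.74 ± 0.12 (adjusted p = 0.000787). The second probe set of Gng13 had a log2 change of -0.14, and 1 of the 3 probe sets of Amot passed while another had a change of -0.07.

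The remaining 5 of the 12 largest rises lay between 2.49 and 2.64 on the log2 scale. Ppp1r13b, which encodes the p53-binding protein ASPP1, rose by 2.64. Spns2, a transporter of sphingosine-1-phosphate, rose by 2.53 from 267 ± 29.6 to 1618 ± 77.0. Slc30a1, a zinc exporter, rose by 2.5 and both of its probe sets passed. Wnk4, a kinase that regulates ion transport, rose by 2.49 from 19 to 179, and 4930550C14Rik rose by 2.54.

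Tac2, which encodes the precursor of neurokinin B, fell from 508 ± 125 to 93.8 ± 28.2, a log2 change of -2.26 ± 0.24 (SE, adjusted p = 0.0436). Klf6, a zinc finger transcription factor, fell in 1 of 5 probe sets, by 0.89 on the log2 scale, while its brightest probe set had a change of -0.39 (adjusted p = 0.237). 4930447F24Rik fell in 1 of 3 probe sets, by 1.24, and its brightest had a change of -0.69 (adjusted p = 0.640). By rule the next genes in order of p are named as well, although they did not pass. Slc26a1, a sulfate transporter, had a log2 change of -1.0 (adjusted p = 0.0611), and Prxl2a, a peroxiredoxin-like protein, had intensities of 12800 ± 1370 and 6583 ± 615, a log2 change of -0.96 (adjusted p = 0.0812).

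**Figure D2:**
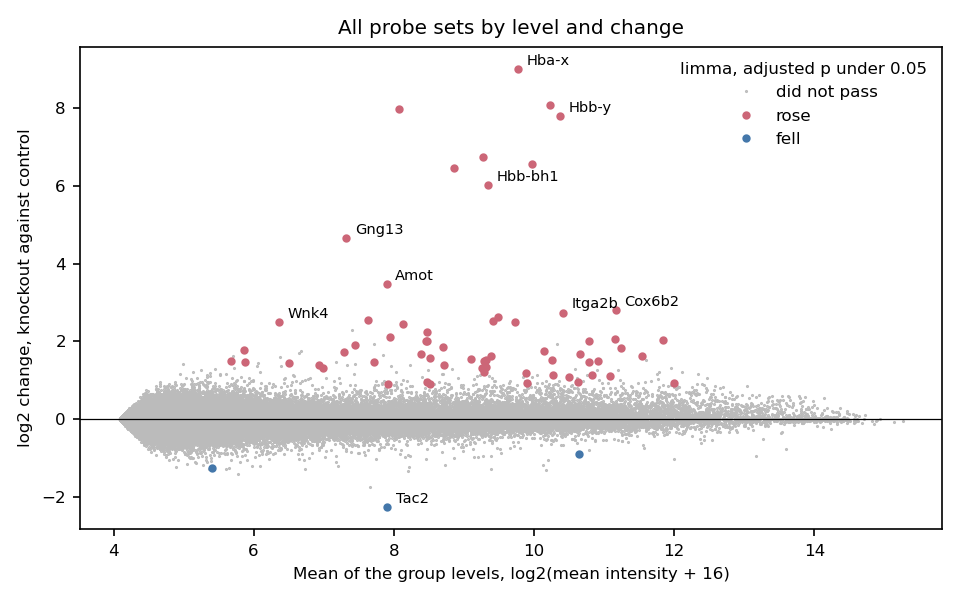
Log2 change of every probe set between knockout and control against its mean level, on the log2(intensity + 16) scale, with the 63 probe sets that rose in red and the 3 that fell in blue. The embryonic globins stand above all other named genes, and the calls spread over most of the intensity range.

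**Figure D3:**
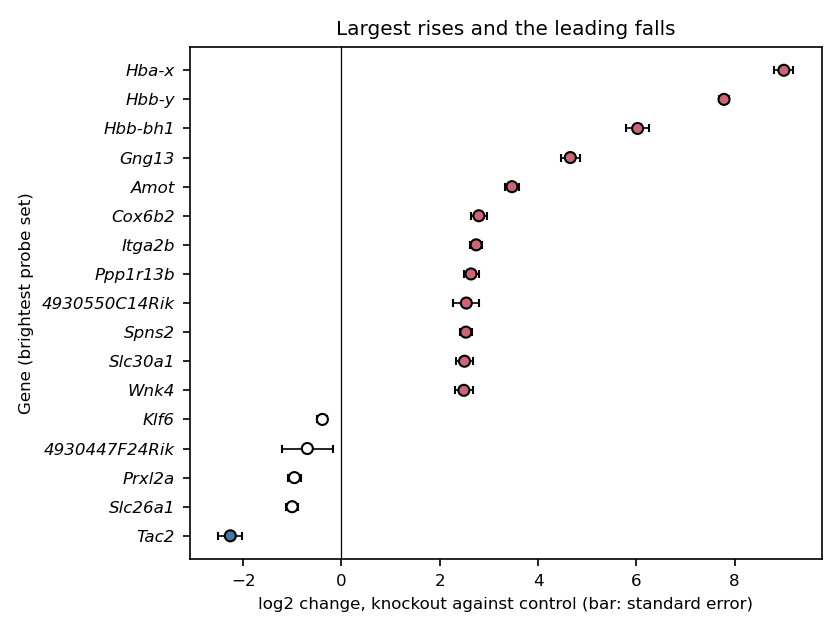
Log2 change between knockout and control, with its standard error, for the 12 genes with the largest rises and the 5 leading falls, each read by its brightest probe set. Filled points passed the test and open points did not; the rises run from 2.49 for Wnk4 to 9.0 for Hba-x, and Tac2 had the lowest change, -2.26.

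In all 66 probe sets that passed, the values of the groups did not overlap, which passing so strict a test nearly requires. Over all probe sets tested the groups did not overlap in 19.5%, against 10% by chance. The count depended on how the variances were moderated, since a fit with an intensity trend and robust moderation called 1206 rises and 239 falls, including all 66. The call of Tac2 ended on leaving out any 1 of the 6 mice (adjusted p = 0.101 to 0.241), as did those of Klf6 (adjusted p = 0.124 to 0.232) and 4930447F24Rik (adjusted p = 0.127 to 0.212). That of Slc30a1 ended without knockout mouse 1 (adjusted p = 0.0555), that of Wnk4 without control mouse 3 (adjusted p = 0.0573) or knockout mouse 1 or 3 (adjusted p = 0.0810 and 0.0769), and that of 4930550C14Rik without any mouse other than control mouse 3 (adjusted p = 0.0645 to 0.218). A pseudocount of 1 ended the calls of Tac2 (adjusted p = 0.120), Klf6 (adjusted p = 0.0827), 4930447F24Rik (adjusted p = 0.109), Wnk4 (adjusted p = 0.0662) and 4930550C14Rik (adjusted p = 0.128), and quantile normalization that of Tac2 (adjusted p = 0.0501).

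Genes of the mature red cell stood higher as groups in the knockout, with modest changes per gene. Of 23 measured genes of the red cell membrane and skeleton, 1 rose, none fell and 22 did not pass over all probe sets; adjusted over the list alone, 15 rose and 1 fell. Add2, the beta subunit of the skeleton protein adducin, rose from 898 ± 187 to 2859 ± 326 (SD, n = 3), by 1.67 ± 0.18 on the log2 scale (SE, adjusted p = 0.0407), and 3 of its 5 probe sets passed. Rhag, the Rh-associated glycoprotein, had a log2 change of 0.91 ± 0.12 (adjusted p = 0.0736), Tmod1, an actin-capping protein, one of 0.97 ± 0.16, and Epb42, the protein 4.2 that ties the skeleton to the membrane, one of 0.75 ± 0.15. Cd59a, an inhibitor of complement named here after its value was seen, was the 1 member that fell within the list, by 0.67. The median of the list was 0.62 (camera, adjusted p = 1.73e-10, and adjusted p = 0.495 with an estimated correlation).

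Of 14 genes of heme synthesis, none passed over all probe sets, and 8 rose and none fell adjusted over the list alone. Abcb6, a porphyrin transporter, had a log2 change of 0.84 ± 0.13 (adjusted p = 0.0992), Alad, the enzyme that forms porphobilinogen, one of 0.71 ± 0.15, and Cpox, coproporphyrinogen oxidase, one of 0.48 ± 0.12. Of 26 erythroid transcription factors, none passed over all probe sets, and 12 rose and none fell adjusted over the list alone. They included Cbfa2t3 (log2 change 0.78 ± 0.11), a corepressor of the Tal1 complex, Tal1 itself (0.91 ± 0.18) and Zfpm1 (0.65 ± 0.14), the cofactor of Gata1. Of 25 genes of late erythroid maturation, none passed over all probe sets, and 6 rose and none fell adjusted over the list alone, among them Ypel4 (0.95 ± 0.17) and the glycine transporter Slc6a9 (0.89 ± 0.20). Of 17 genes of iron uptake and storage, none passed over all probe sets, and 1 rose and none fell adjusted over the list alone. That gene was Steap3, the ferric reductase of the transferrin cycle, with a log2 change of 1.22 ± 0.18. The median changes were 0.48 for heme synthesis (camera, adjusted p = 2.55e-05), 0.30 for the transcription factors (adjusted p = 1.68e-06), 0.27 for late maturation (adjusted p = 8.37e-07) and 0.13 for iron (adjusted p = 0.00451). Each of these 4 calls was lost as well (adjusted p = 0.495 with an estimated correlation, for each list). The call of the iron list also ended after quantile (adjusted p = 0.0623) or cyclic loess normalization (adjusted p = 0.0628) and in the brightest 25% of probe sets (adjusted p = 0.102), and the call of Add2 ended on leaving out any 1 of the 6 mice (adjusted p = 0.0609 to 0.237), after quantile normalization (adjusted p = 0.0534) and with a pseudocount of 1 (adjusted p = 0.114).

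Genes of cell division stood higher in the knockout as well. Of 27 genes of the mitotic cell cycle, none passed over all probe sets, and 8 rose and none fell adjusted over the list alone. All 27 had a log2 change above 0, and 20 had all 3 knockout values above all 3 control values. Tpx2, a spindle assembly factor, had a log2 change of 0.56 ± 0.11, the kinase Plk1 one of 0.40 ± 0.10, and Birc5, or survivin, one of 0.38 ± 0.10. The median was 0.33 (camera, adjusted p = 6.26e-11, and adjusted p = 0.495 with an estimated correlation). Of 32 genes of DNA replication, none passed over all probe sets or adjusted over the list alone. The S-phase cyclins Ccne2 and Ccne1 had log2 changes of 0.62 ± 0.15 and 0.46 ± 0.14, and the list's median was 0.10 (camera, adjusted p = 0.0211, and adjusted p = 0.804 with an estimated correlation). The replication call also ended after quantile (adjusted p = 0.454) or cyclic loess normalization (adjusted p = 0.260), in the brightest 25% of probe sets (adjusted p = 0.176), with the mean of all probe sets of a gene (adjusted p = 0.0922) and without control mouse 1 (adjusted p = 0.105) or knockout mouse 3 (median 0.04, adjusted p = 0.414), while the median was 0.16 without knockout mouse 1.

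Of 21 heat shock and antioxidant genes, none passed over all probe sets, and 1 rose and none fell adjusted over the list alone. That gene was Nqo1, a quinone reductase, with a log2 change of 0.77 ± 0.15. Other antioxidant genes such as Txnrd1, thioredoxin reductase (0.36 ± 0.10), and Gclm, of glutathione synthesis (0.50 ± 0.14), did not pass, and the median was 0.31 (camera, adjusted p = 4e-04, and adjusted p = 0.495 with an estimated correlation), and 0.20 without knockout mouse 3. Of 39 proteasome genes, none passed over all probe sets or adjusted over the list alone; Psmd10 had a log2 change of 0.47 and Psmc2 one of 0.34. Their median was 0.14 (camera, adjusted p = 0.0156, and adjusted p = 0.495 with an estimated correlation). The proteasome call also ended after quantile (adjusted p = 0.735) or cyclic loess normalization (adjusted p = 0.354), in the brightest 25% of probe sets (adjusted p = 0.0720) and without knockout mouse 2 (adjusted p = 0.0572).

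Genes of earlier progenitors stood lower as a group. Of 21 such genes, none passed over all probe sets or adjusted over the list alone. Myb, a transcription factor of proliferating progenitors, had a log2 change of -0.42 ± 0.14, Cdk6 one of -0.36 ± 0.12, and Cd34, a stem and progenitor cell antigen, one of -0.51 ± 0.19. In all, 17 members had changes below 0 and 4 above, among them Tfr2 at 0.32. The list shares Ctsg (-0.25) with the neutrophil markers and Gata2 (-0.30) with the basophil markers. A lower share of other cells in the sort therefore cannot be told apart from a fall in erythroid progenitor genes. The list's median was -0.24 (camera, adjusted p = 5e-04, and adjusted p = 0.495 with an estimated correlation). Of 21 genes of glycolysis and hypoxia, none passed over all probe sets or adjusted over the list alone, and the median was -0.15 (camera, adjusted p = 0.0231, and adjusted p = 0.495 with an estimated correlation). Within it Pgk1, a glycolytic kinase, had a change of -0.26 and Hk1, hexokinase 1, one of 0.52. The glycolysis call also ended without control mouse 1 (adjusted p = 0.0964) or knockout mouse 2 or 3 (adjusted p = 0.0660 and 0.0786).

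Markers of other bone marrow cells were measured in the sorted cells, with 19 of the 21 B cell markers, 18 of the 18 neutrophil markers, 17 of 23 for monocytes and macrophages, 9 of 12 for basophils and their kin, 7 of 18 for T and NK cells, 4 of 20 for stroma and 3 of 16 for megakaryocytes above the upper quartile of mean levels. Of 21 B cell markers, none passed over all probe sets, and 5 fell and none rose adjusted over the list alone. Igll1 and Vpreb1, the surrogate light chain genes of early B cells, had log2 changes of -1.31 ± 0.23 and -1.19 ± 0.24, with Igll1 at 1783 ± 285 in the controls and 727 ± 231 in the knockouts (SD, n = 3). The median of the B cell list was -0.36 (camera, adjusted p = 5e-04, and adjusted p = 0.586 with an estimated correlation), and -0.18 without knockout mouse 3 (adjusted p = 0.0158). Of 18 neutrophil and granule markers, none passed over all probe sets or adjusted over the list alone. Ltf, lactoferrin, had an intensity of 21483 ± 948 in the controls and 19632 ± 853 in the knockouts, a log2 change of -0.13, and Ctsg, cathepsin G, had one of -0.25. The neutrophil median was -0.08 (camera, adjusted p = 0.0277, and adjusted p = 0.495 with an estimated correlation), and -0.19 after cyclic loess normalization.

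Of 12 basophil, eosinophil and mast cell markers, none passed over all probe sets or adjusted over the list alone; Mcpt8, a basophil protease, had a log2 change of -0.42. The median of that list was -0.19 (camera, adjusted p = 0.0141, and adjusted p = 0.605 with an estimated correlation), -0.29 without knockout mouse 1 and -0.09 without knockout mouse 3. Lists of monocytes and macrophages (23 genes, camera adjusted p = 0.847), of T and NK cells (18 genes, 0.867) and of stromal and endothelial cells (20 genes, 0.380) did not pass and had no member that passed over all probe sets or adjusted over the list alone. In the list of 16 megakaryocyte and platelet genes, Itga2b rose and the other 15 did not pass (camera, adjusted p = 0.720). The platelet genes Vwf and Gp5 had log2 changes of 0.26 and 0.42, and Gp6 had one of -0.45. The neutrophil call ended without any mouse other than control mouse 3 and knockout mouse 3 (adjusted p = 0.0637 to 0.112), and the basophil call without control mouse 2 (adjusted p = 0.111) or knockout mouse 3 (adjusted p = 0.200).

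**Figure D4:**
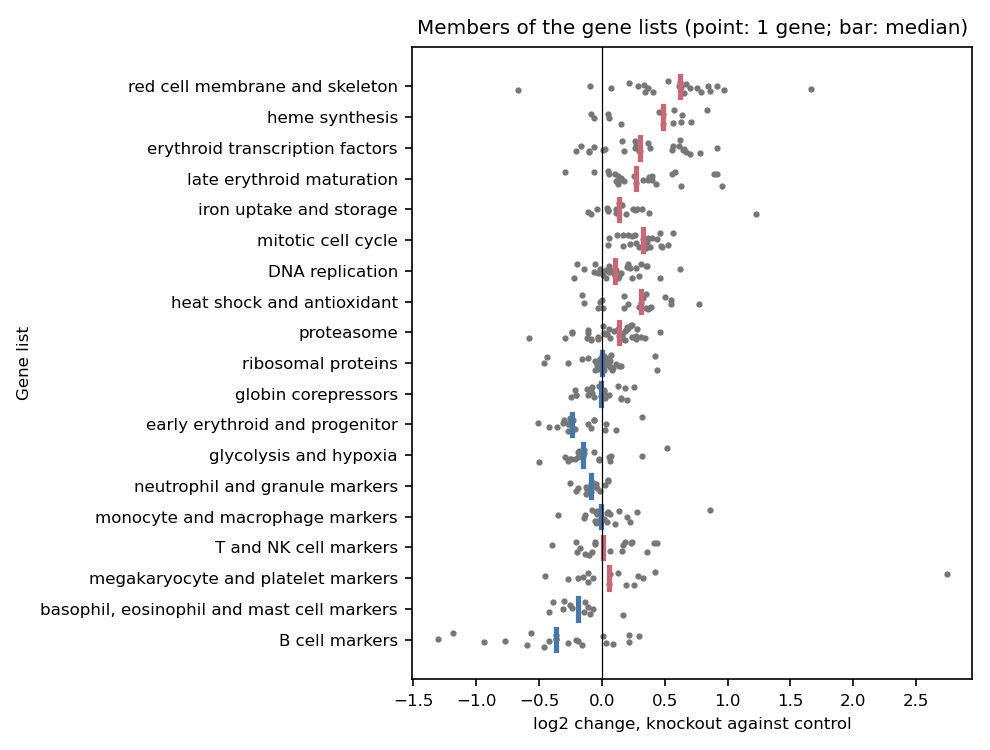
Log2 change between knockout and control of the members of 19 gene lists, with 1 point per gene and a bar at each list's median, red above 0 and blue below. The red cell membrane list has the highest median, 0.62, and the B cell list the lowest, -0.36.

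Signalling and stress lists gave mixed pictures. Of 15 genes of the erythropoietin receptor and its targets, none passed over all probe sets, and 2 rose and 2 fell adjusted over the list alone. The kinase Pim1 (log2 change 0.86 ± 0.12) and the feedback inhibitor Cish (1.00 ± 0.16) rose within the list, while Osm, or oncostatin M (-0.42 ± 0.12), and Socs2, another feedback inhibitor (-0.86 ± 0.24), fell. Epor itself had a log2 change of -0.14. The list as a whole did not pass (camera, adjusted p = 0.782). Of 22 p53 targets, none passed over all probe sets and 2 rose adjusted over the list alone, Gadd45a (0.64 ± 0.09) and Sesn1 (0.62 ± 0.10), both induced by stress (camera, adjusted p = 0.720). Plk2 (-0.33) and Cdkn1a (-0.30) had changes the other way. In 3 members every knockout value lay above all controls, and in 4 below. Of 26 genes of the integrated stress and unfolded protein responses, none passed over all probe sets and 2 rose adjusted over the list alone, Eif2ak1, the heme-regulated kinase of eIF2 alpha (0.77 ± 0.14), and Slc3a2, an amino acid transporter chain (0.64 ± 0.14). Its members Atf3 (-0.91) and Phgdh (-0.54) had changes the other way and did not pass. That list did not pass either (camera, adjusted p = 0.847).

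Of 11 genes of the fetal programme, none passed over all probe sets and 1 rose adjusted over the list alone, Arid3a, a transcription factor (0.84 ± 0.12), and the list did not pass (camera, adjusted p = 0.221). The 25 globin corepressors (adjusted p = 0.745), the 14 genes flanking Bcl11a (adjusted p = 0.889), the 19 flanking Epor (adjusted p = 0.745) and the 48 ribosomal proteins (adjusted p = 0.978) had no member that passed over all probe sets or adjusted over the list alone, and none of these lists passed. The ribosomal median was near 0, and cyclic loess normalization moved it to -0.10 (adjusted p = 0.00210). The same held for cholesterol synthesis (19 genes, adjusted p = 0.128) and the interferon response (26 genes, adjusted p = 0.174), where the interferon list passed without control mouse 2 (adjusted p = 0.000795) or knockout mouse 2 (adjusted p = 0.00298) and the cholesterol list without knockout mouse 3 (adjusted p = 0.0293). Of 75 genes of oxidative phosphorylation, Cox6b2 rose, and adjusted over the list alone 2 rose and 1 fell. Besides Cox6b2 these were Ndufb9, a subunit of complex I (0.75 ± 0.10, with another of its 3 probe sets past the test over all probe sets), and Cox6a2, a muscle form of a cytochrome c oxidase subunit (-0.55 ± 0.10). That list did not pass (camera, adjusted p = 0.0647), although it did with an intensity trend (adjusted p = 0.0158), after median centring (adjusted p = 0.0378), with a pseudocount of 64 (adjusted p = 0.0397), with the mean of all probe sets of a gene (adjusted p = 0.0493) and without control mouse 3 (adjusted p = 0.0415) or knockout mouse 1 (adjusted p = 0.0404).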

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

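In this part, the test of cyclic loess scaling and that of probe sets bright in the controls were chosen after the data were seen, as was the reading of the test in the brightest 25% of probe sets, and the unnamed probe sets were picked out because they passed the test. 4 probe sets that passed carry no gene name in the annotation used here and so belong to no gene comparison, and each was higher in the knockout than in the controls (limma, SD over 3 mice). The brightest had an intensity of 4286 ± 609 in the knockouts and was listed at 1 on all 3 control arrays, a value that 775 to 874 probe sets share on each array, so no ratio is given (adjusted p = 5.90e-06). The next had 920 ± 112 against 303 ± 29.3 in the controls, and the third 497 ± 42.9 against 104 ± 29.5 (adjusted p = 0.0185 for both). The dimmest had 68.8 ± 6.28 against 14.6 ± 5.43 (adjusted p = 0.0361). Which transcripts they read was not worked out here.

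Rises outnumbered falls among the probe sets that passed, 63 to 3. They made up at least 95.5% of calls under quantile, median and cyclic loess scaling, so the choice among these scalings does not explain the imbalance. The deposited arrays were already at a common level, and these scalings left the median change of all probe sets between -0.0166 and 0.0129. Whether the deposited scaling contributed therefore cannot be decided by this test. Probe sets too dim to fall are argued against as the whole cause, since of 24 genes called above the upper quartile of control means 22 rose and 2 fell, or 91.7% rises (exact 95% interval 73% to 99%, too narrow in that it takes genes from the same mice as independent), and on leaving out any 1 mouse 7 to 9 rose there and 0 fell. The planned comparison went the way of this cause, since rises were 78.7% of calls in the brightest 25% of probe sets, under a bound of 80% set beforehand. It was set aside after the data were seen, because that fit made 1654 calls, 1302 of them rises. An intensity trend with robust moderation on all probe sets gave 83.5%. The share of rises thus depends on the fit, and dim probe sets as a part of the cause stay open. The real split of the 6 arrays gave 66 calls and was the only 1 of 10 splits with as many, the highest of the others being 0; 10 splits are too few for a share under 0.05. Loss of a repressor, the biological explanation that the groups give, stays open, as does an effect of Cre, which was named for the knockout mice only. A difference in strain background, which is not given in the sources used here, stays open as well.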

How the results depend on the processing

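Cyclic loess normalization and the removal of probe sets with a value of exactly 1.00 were chosen after the data were seen, and the other alternatives beforehand. Hba-x (7.83 to 9.75), Hbb-y (7.17 to 8.05) and Hbb-bh1 (5.35 to 6.33) rose past the threshold under all 18 alternatives. The brightest Bcl11a probe set kept a change between -0.28 and -0.14 and passed under none. No named gene that passed the test changed direction. The counts moved far more. In the order probe sets higher, probe sets lower, genes higher and genes lower, the main counts were 63, 3, 44 and 3. They were 38, 0, 26 and 0 with a pseudocount of 1, and 508, 50, 347 and 38 with one of 64. They were 708, 145, 475 and 105 in the brighter 50% of probe sets and 1302, 352, 882 and 284 in the brightest 25%. With an intensity trend and robust moderation they were 1206, 239, 779 and 172. Over all probe sets that fit called 13 of 27 mitotic genes, 8 of 14 heme synthesis genes and 10 of 26 erythroid transcription factors higher. It called 12 of 23 red cell membrane genes higher and 1 lower, and 4 of 21 B cell markers lower. With array weights 5 probe sets and 5 genes were lower, and with 1 probe set per gene 77 genes were higher and 7 lower. The variance estimates and the number of probe sets tested differ between these fits, and beyond that the cause was not tested. Without 1 mouse the counts were 27 to 41, 0 to 1, 18 to 30 and 0 to 1, with fewer samples in each such fit, and leaving out any of the 6 mice moved the first count over 1.5 times. Of the 66 probe sets, 25 passed in all 14 settings that keep every probe set, the replicate block left out, and they stood for 18 genes. With the block counted as well, 14 probe sets passed in all 15 settings, and they stood for 9 genes.

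With the replicate number as a block, 14 probe sets and 9 genes were higher and 0 and 0 lower. Mice with the same number did not deviate together (r = -0.03, -0.01 and -0.04 across probe sets), and r lay between -0.0068 and 0.0402 for unlike numbers. No pairing was seen, but such values cannot exclude one, so a weaker effect under the block stays open. The block ended 6 calls among the brightest probe sets of the named genes. They included Ppp1r13b (adjusted p = 0.0807), Slc30a1 (adjusted p = 0.121), Wnk4 (adjusted p = 0.152) and Tac2 (adjusted p = 0.413). As 0 probe sets were lower, the calls of Klf6 and 4930447F24Rik through other probe sets ended too. Of the 29 gene lists, 14 passed in the main setting, 0 with an estimated correlation and 11 to 15 under the others. The median of the ribosomal proteins, near 0 in the main setting, was -0.10 after cyclic loess normalization (adjusted p = 0.00210); the cause was not tested. No scaling moved the median change of all probe sets beyond -0.0166 or 0.0129. Without detection calls, probe sets near the lowest values limit what can be said of low levels.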

Other observations

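In this part, the tests of other cells' markers, of mitotic genes, of the iron list and of the other probe sets of neighbouring genes, and the count on the chromosome of Bcl11a, were chosen after results were seen, and the genes named in the first 2 paragraphs were picked after their values were seen. Several further genes that rose fall outside the rule for named genes. Pepd, which encodes the dipeptidase prolidase, rose by 2.06 ± 0.09 on the log2 scale (limma, SE, adjusted p = 0.000977). Tnk2, a tyrosine kinase, rose by 2.02 ± 0.12, with both of its probe sets past the test. Aftph, a vesicle trafficking protein, rose by 2.02 ± 0.11 and all 5 of its probe sets had changes above 0. Klhdc2, a substrate receptor of a ubiquitin ligase, rose by 1.62 ± 0.09, Gcn1, an activator of the kinase Gcn2, by 1.5 ± 0.13 in 1 of 5 probe sets, with changes of -0.45 and -0.13 in 2 of the others, and Mllt3, a chromatin reader of the super elongation complex, by 1.12 ± 0.10. The call of Gcn1 ended on leaving out any mouse other than control mouse 1 (adjusted p = 0.107 to 0.168) and that of Mllt3 on leaving out any 1 of the 6 (adjusted p = 0.0693 to 0.168).

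A fit with an intensity trend and robust moderation called further falls that the default fit did not. Cd69, a surface antigen of activated leukocytes, had a log2 change of -1.27 (adjusted p = 8.73e-05 with the trend), and Rgs1, a regulator of G protein signalling in leukocytes, one of -0.94 (adjusted p = 0.000253). Fosb and Jun, subunits of the AP-1 transcription factor, had changes of -1.34 (adjusted p = 0.000314) and -0.61 (adjusted p = 0.0178). Thbs1, or thrombospondin, had -0.73 (adjusted p = 0.00192) and Dusp6, a phosphatase of ERK, -0.51 (adjusted p = 0.0122). Tac2 and Prxl2a were called lower in this fit (adjusted p = 5.87e-05 and 3.82e-05), and the adjusted p of Prxl2a without the trend was 0.0812. Rhag, of the red cell membrane, was called higher with the trend (adjusted p = 3.08e-05).

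Erythroid lists stood higher and the B cell list lower in the knockout. A common drop in the share of all other cells cannot be told apart, since well-measured B cell markers changed by -0.267 relative to neutrophil and -0.424 relative to monocyte and macrophage markers (mean log2 change), but over the 3 mice per group neither difference passed (t-test, lowest Holm-adjusted p = 0.0699 over 3 pairs of cell types, 0.0233 unadjusted), and the first was -0.365 to -0.162 on leaving out 1 mouse. An intensity-dependent shift between arrays is argued against, since the membrane, transcription factor and mitotic lists lay at percentile 99.99 or above among 10000 random lists matched on expression, but the iron list, at percentile 95.84, is within what such a shift could give. A shift toward late cells that no longer divide would lower mitotic genes, and no such fall was seen. All 27 were above 0, with a median of 0.33 (fry, p = 0.0149 and adjusted p = 0.0856 over the lists, against camera's p = 0.123 with an estimated correlation). The rise did not pass over the lists, and a lower share of other cells, left open above, could bear on it too. Whether such a shift took place therefore cannot be decided by this test. A different mix of dividing erythroid stages in the sort, or an effect of Bcl11a on these genes, may each contribute, and 3 mice per group do not separate them.

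Aftph and Lgalsl, a galectin-like gene, were the only 2 genes, globins left out, that rose and have a called neighbour within 5 measured genes, and they are adjacent in the assembly GRCm38.p6, 23 and 22 measured genes from Bcl11a on the same chromosome. Chance placement could give as many, since random draws of 39 genes did so often (one-sided permutation p = 0.365). A sequence variant under single probes is argued against for Aftph, since its 2 probe sets that did not pass had higher values too, with 95% lower bounds of 0.67 and 0.384 on the log2 scale, at control means of 100.42 and 27.55; for Lgalsl it cannot be told apart, since 0 such probe sets are left. On the chromosome of Bcl11a lay 7 of the 39 placed genes or 17.9% against 8.10% of measured genes (Fisher's exact test, two-sided, p = 0.0356). This test takes genes as independent. The other 5 lay between 138 and 1195 measured genes from Bcl11a. The list of 14 genes flanking Bcl11a did not pass (camera, adjusted p = 0.889), but camera asks for a shift in 1 direction. In 4 members every knockout value lay above all controls and in 3 below, where 19.5% of all probe sets did not overlap. A test for changes in either direction gave an adjusted p of 0.0147 (fry, mixed), and 0.00094 for the ribosomal proteins. Changes near Bcl11a therefore stay open. Whether a difference in strain background contributes was not tested.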
